A study of Caenorhabditis elegans with 2 samples.

How the data were processed

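Chromatin immunoprecipitation followed by sequencing was done on whole L2 hermaphrodites of strain OP109, and the deposited peak lists of 2 biological replicates, numbered 2 and 3 per the labels, were analysed. Chromatin was sheared by sonication per the labels. The antibody field of the labels names BLMP-1; whether an antibody against the tag was used is not given in the sources used here. Per the deposited file descriptions, relaxed lists (peaks together with background, made as input for a reproducibility analysis) were called for each replicate and for the pooled replicates against a control library, and a thresholded list was derived from those 3 lists. The control library is not analysed here. The aligner, the peak caller, their versions and the reproducibility threshold are not given in the sources used here.

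Each list gives a peak's start, end, signal, significance and summit. The signal values were deposited by the authors as made by their caller, and their scale is not given in the sources used here. The deposited −log10 q values (per the narrowPeak layout) reached a ceiling of 3.98 in every thresholded peak and were not used to rank peaks. Signal was used to rank or describe peaks within 1 list, and between the replicates only in a rank correlation. The pooled list has exactly 30000 peaks, which has the form of a cap, and the thresholded list of 3060 peaks holds exactly the 3060 peaks of highest signal in the pooled list. Some regions have several summits: 10 thresholded peaks repeat the interval of another peak, and 3 summits given outside their interval were set to its last base. No list gives read counts, so depth is unknown, and the Wilson intervals cover only the counting of peaks.

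Lists on ce11 were the main ones; ce11 is the same assembly as WBcel235, and no peak passed the end of its chromosome in that reference. Lists on ce10 were used for the overlap of replicates only, with the last peak end of each chromosome as its length, and no coordinates were converted. Genes came from Ensembl release 115. MicroRNA genes were named by matching coordinates to the RefSeq annotation. The nuclear protein-coding genes numbered 19973. The 29 thresholded peaks on mitochondrial DNA were left out of all location, gene and motif tests, but stayed in the ranking that sets the 3060 strongest peaks. Coordinates are 1-based.

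The replicates were compared by the share of the 3060 strongest peaks with reciprocal overlap of at least 50%, against 1000 circular shifts (one-sided). The promoter share was tested against 1000 circular shifts of the summits (two-sided); the window ran from 1000 bp upstream to 200 bp downstream of any transcript start of a protein-coding gene. A summit was placed in the first class that applied, in the order promoter window, coding exon, UTR, other exon, intron, remaining sequence. Gene lists were tested with Fisher's exact test (two-sided) against all other protein-coding genes, with Benjamini-Hochberg adjustment over 20 lists; the microRNA list was tested against the other microRNA genes. One intestinal marker, opt-2, found no gene of that name, so 17 were tested. AGYGAAAG was counted within 50 bp of the summit and in windows 1000 bp to each side (exact McNemar test), and all 8-mers were scanned in the same way. The correlation of motif and signal used 100000 permutations, and the X share an exact binomial test. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9.

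The lists, tests, motif and alternatives were fixed before the data were examined, except where stated. The rule for named genes took blmp-1 and unc-119, the genes at the 10 strongest promoter peaks, every heterochronic gene and microRNA, up to 4 members with the strongest promoter peak in each list past the adjusted threshold of 0.05 and up to 2 in each other list, with all protein-coding genes sharing the summit. Alternatives were windows of 500 and 2000 bp upstream, the stronger 1530 peaks, the strongest peaks of the pooled list, the 3060 strongest peaks of either replicate alone, other overlap rules and numbers of peaks, other motifs and windows, the nearest gene start, and 10000 random lists matched on the upstream intergenic gap.

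The statistics were tested on simulated data first. With 40% of 3000 simulated peaks planted as shared, the overlap step found 40.6%. The shared peaks were exact copies of equal width, so this run does not show how the overlap rule treats peaks of unequal width. Of 200 unrelated lists drawn from 20000 simulated genes, 4.5% passed an unadjusted 0.05. An 8-mer planted in 6% of 1000 windows ranked 1, with 0 other words past the adjusted threshold. The simulated summit and flank windows had the same base composition, unlike the real ones. That run therefore does not show how many words pass in the data for reasons of composition.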

Results

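BLMP-1 is the worm relative of the mammalian zinc finger repressor PRDM1 (Blimp-1) and acts in the epidermis and in the timing of larval development. Its binding was mapped by chromatin immunoprecipitation and sequencing in whole hermaphrodite Caenorhabditis elegans at the L2 larval stage. The strain OP109 carries a transgene of BLMP-1 with a C-terminal GFP-FLAG tag in an unc-119 mutant background. The data were 2 biological replicates of 1 group, numbered 2 and 3 in the labels, with no other genotype or stage to compare. The relaxed peak lists held 19553 peaks for replicate 2 and 25142 peaks for replicate 3 on the ce11 build, and 30000 peaks for the pooled replicates. The thresholded list, which rests on both replicates, held 3060 peaks, 3031 of them on nuclear chromosomes. Read counts per library were not among the values used here, so the sequencing depth is unknown, and every peak signal below is the authors' own value; values are compared within a list, and between lists only by rank.

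The strongest nuclear peaks lay at genes of several kinds, and the ranks below refer to the nuclear thresholded peaks. The strongest of all, with a signal of 858, was in an intron of ccch-1 on chromosome V (11532970 to 11533394). The peaks ranked 2 and 6, with signals of 721 and 505, lay between tag-353 and blmp-1 itself, upstream of blmp-1, on chromosome I, with summits at 10405076 and 10406211. Others were in introns of the cyclic GMP-dependent protein kinase gene egl-4 (chromosome IV, summit 1866997, signal 533), the casein kinase gene kin-20 (chromosome X, summit 15276919, signal 437) and the calcium/calmodulin-dependent kinase gene unc-43 (chromosome IV, summit 10342544, signal 433). The non-promoter peaks in this paragraph were singled out after their values were seen.

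Among summits in promoter windows, the strongest had a signal of 463 and lay on chromosome V at 15143999, 20 bp from the nearest transcript start of K08F9.4 and 614 bp from that of K08F9.1. That summit also lay within a further gene, K08F9.3, though not in its promoter window. Next came the peak 227 bp from W03F8.4 on chromosome IV (summit 5183896, signal 426) and the peak 244 bp from the start of blmp-1 on chromosome I (summit 10409058, signal 421). The promoter of edc-4 (chromosome I, summit 3350038) had a signal of 381. One summit on chromosome III at 4899936, with a signal of 338, lay in the windows of nhl-2, a cofactor of the microRNA machinery, and tag-340. The promoter of dpy-31, an astacin protease gene needed for collagen processing, had a signal of 323 (chromosome III, summit 7201529). The remaining promoters in the group of 10 were those of rpl-3 (signal 317), lgg-2 (signal 279), F56C9.10 (signal 278) and atf-2 (signal 265). The 12 genes named here for a promoter window all had a promoter summit among the 3060 strongest peaks of replicate 2 and of replicate 3.

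The first comparison asked how far the replicates found the same sites. Of the 3060 strongest peaks of replicate 2, 1774 (58.0%) overlapped a peak among the 3060 strongest of replicate 3 by at least 50% of both intervals. Peaks moved by a random offset along each chromosome gave a mean of 0.988% and at most 1.73% (one-sided permutation test, p = 0.001, the smallest value that 1000 shifts can give). In the other direction 57.9% of the peaks of replicate 3 were shared. The share of replicate 2 depended on the rule, at 68.8% for overlap of at least 1 bp and 62.0% for summits within 100 bp. By the reciprocal rule it did not rise steadily with peak strength, at 61% among the 100 strongest peaks and 49.8% among the 1000 strongest. Among thresholded peaks, 99.0% touched a relaxed peak of replicate 2 and 99.8% one of replicate 3. The thresholded list was derived from the relaxed lists, so these shares were largely fixed in advance and say little about the replicates. The required overlap of both intervals was met less often in the stronger 1530 peaks (65.0% in replicate 2) than in the weaker 1530 (95.2%). The stronger peaks had a median width of 248 bp and 39.5% of them had the list's most common width of 336 bp, against a median of 336 bp and 98.3% in the weaker peaks. Across 2806 nuclear peaks with a summit within 100 bp in both replicates, Spearman's rho of the signals was 0.562. That value is across peaks, which are not independent replicates.

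The second comparison asked where the summits lay relative to genes. Promoter windows, from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start, held 1513 of the 3031 nuclear summits (49.9%, 95% Wilson interval 48.1 to 51.7). Shifted summits fell there in 25.8% of cases, so the observed share was 1.94 times as high (two-sided permutation test, p = 0.001, the smallest value that 1000 shifts can give). Introns outside the windows held 523 summits (17.3% against 27.4% of shifted summits, permutation p = 0.001), and coding exons held 27 (0.891% against 18.96%, p = 0.001). Sequence outside genes and promoter windows held 933 summits (30.8% against 25.1%, permutation p = 0.001). The 3' UTRs held 22 summits (0.726% against 2.40%, permutation p = 0.001), and the 13 summits in 5' UTRs did not differ from the shifted ones (p = 0.168). The median distance of a summit to the nearest transcript start was 803 bp, and 777 summits (25.6%) lay beyond 2000 bp. Many worm transcripts are trans-spliced, so annotated transcript starts are approximate.

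In all, 1765 of the 19973 nuclear protein-coding genes (8.84%) had a promoter summit. Among these genes 97 had at least 2 summits. The most, 5, were at din-1, which encodes a corepressor of the nuclear receptor DAF-12 and was singled out after its value was seen. In the 500 bp window din-1 had 1. Of the 1513 promoter summits, 342 lay in the windows of 2 or more genes, where the peak lists cannot assign the summit to 1 of them. With the stronger 1530 peaks alone the count of genes was 873.

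The heterochronic genes, which set the timing of larval cell fates, had promoter summits far more often than other genes. Of the 16 members, 9 had one (56.2%), against 8.80% of other protein-coding genes (odds ratio 13.3, 95% interval 4.41 to 42.1, Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 1.04e-05 over 20 lists). The odds ratio fell to 6.19 with a 500 bp window (exact test, adjusted p = 0.0139) and to 7.32 with the stronger 1530 peaks (0.0173), and rose to 17.3 with assignment to the nearest gene start. The strongest were nhl-2 (signal 338, shared with tag-340), kin-20 (232, with 3 promoter summits), ain-1 (85.2, with 2) and lin-14 (56.0). The promoters of lin-42 (42.3), lin-29 (35.6), lin-28 (35.1), alg-1 (35.0) and hbl-1 (32.2) also held summits. With the 500 bp window nhl-2, ain-1, lin-42 and hbl-1 had none. Among the stronger 1530 peaks, none was a promoter summit of lin-42, lin-29, lin-28, alg-1 or hbl-1. Without replicate 2 ain-1 had 1 and hbl-1 none, while lin-28 had none without replicate 3. Every transcript start had its own window, so genes with several starts had more window sequence. Neither the exact test nor the lists matched on the upstream gap took this or gene length into account. The heterochronic genes were longer than others, as given below. The promoter summits of alg-1 and lin-28 and the 2 of lin-42 lay within the gene, as did the strongest of kin-20. No promoter summit was found for daf-12, dre-1, lep-2, lin-41, lin-46, mab-10 or sea-2.

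Several of these 7 genes had peaks farther away. The intergenic peak nearest to lin-41, whose summit lay 1503 bp from its start (chromosome I, 9343999), had a signal of 274 and rank 24. The steroid receptor gene daf-12 on chromosome X held 5 summits within the gene, the strongest at 102. One summit of 48.5 lay upstream of mab-10 and one of 50.8 within sea-2. From 10000 bp upstream to the gene end, 13 of the 16 genes held a summit (81.2%), against 27.2% of other genes, which were shorter (median 2026 bp against 7424 bp). In that window no summit was found for dre-1, lep-2 or lin-46.

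Among the heterochronic microRNA genes, 3 of 5 had a promoter summit, mir-48 (signal 54.05), mir-241 (42.1) and mir-84 (29.6), against 11.3% of the other 256 microRNA genes (odds ratio 11.5, 95% interval 1.27 to 143, Fisher's exact test, adjusted p = 0.0355). The windows of lin-4 and let-7 held none, although both held 1 with a 2000 bp window, and within 10000 bp upstream lin-4 had a summit of 155 and let-7 one of 50.1. A peak with a signal of 165 lay upstream of both mir-48 and mir-241 on chromosome V. These genes lie close together on the same strand, although the exact test counts them as independent. The windows start at the annotated microRNA genes, of median length 96 bp in this list, so they need not lie at primary transcript starts. The call of the exact test rests on 3 genes and was lost with a 500 bp window (odds ratio 8.17, adjusted p = 0.133), with the stronger 1530 peaks (3.98, 0.496), without replicate 3 (10.3, 0.0613) and against lists matched on the upstream gap (7.09, 0.142).

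Genes of molting and of the cuticle were also bound more often. Of 26 molting genes 7 had a promoter summit (26.9%, odds ratio 3.81, 95% interval 1.35 to 9.48, Fisher's exact test, adjusted p = 0.0203). The strongest were the nuclear receptor genes nhr-25 (signal 258, chromosome X, summit 13009107) and nhr-85 (164), followed by the astacin protease gene nas-36 (100.1) and che-14 (87.9), which acts in apical secretion. Of 174 cuticle collagens 33 had one (18.97%, odds ratio 2.44, 95% interval 1.61 to 3.6, Fisher's exact test, adjusted p = 9.21e-05), led by dpy-10 (120), col-149 (114.6) and a summit in the windows of both col-159 and col-160 (81.9). With the stronger 1530 peaks the molting list no longer passed the exact test (adjusted p = 0.0839), although its odds ratio of 3.99 was not lower, and with a 500 bp window it did not pass with an odds ratio of 3.24 (0.0846). For collagens the odds ratio itself fell, to 1.48 with the stronger 1530 peaks (exact test, adjusted p = 0.427) and to 1.55 without replicate 3 (0.143).

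Of 269 nuclear hormone receptor genes 36 had a promoter summit (13.4%, odds ratio 1.61, 95% interval 1.09 to 2.30, Fisher's exact test, adjusted p = 0.0353). The strongest were nhr-25 and nhr-85, as above, then nhr-50 (168) and nhr-135 (117). Without replicate 3 the call was lost (odds ratio 1.502, exact test, adjusted p = 0.104).

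The cytosolic ribosomal protein genes had the highest odds ratio of the 20 lists with the 1000 bp window, though not under every alternative. Of 79 members 54 had a promoter summit (68.4% against 8.60% of other genes, odds ratio 22.9, 95% interval 13.99 to 38.6, Fisher's exact test, adjusted p = 1.65e-37). The strongest were rpl-3 (signal 317), rpl-20 (208, shared with Y17G9B.5), rpl-15 (183, shared with K11H12.8) and rpl-35 (169). With assignment to the nearest gene start the odds ratio fell to 6.98, below those of the heterochronic (17.3), insulin and stress (8.96) and seam and epidermal lists (7.83). With a 2000 bp window it was 20.5, below the 66.5 of the heterochronic microRNA list, which was estimated with 0.5 added to each count because all 5 members had a summit.

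Chemoreceptor genes were bound far less often, with 8 of 1287 members (0.622%, odds ratio 0.0603, 95% interval 0.0259 to 0.119, Fisher's exact test, adjusted p = 2.52e-40). The strongest of those were srh-17 (signal 121), srh-76 (60.9), srh-46 (57.6) and str-176 (47.8). None of the 240 C-type lectin genes had a promoter summit, against 8.94% of other genes (Fisher's exact test, adjusted p = 2.00e-09, upper 95% bound of the odds ratio 0.158). Both families lie in tandem arrays of similar genes, where reads that map to several copies can be lost.

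The other 12 lists did not pass the adjusted threshold of 0.05. The genes nhr-23 and akt-2 below are named beyond the rule for named genes, after their values were seen. Some lists share members, such as nhr-25, which is also in the molting and nuclear hormone receptor lists, and lin-29, which is also in the heterochronic list, so the lists are not independent. Of 14 seam and epidermal transcription factors 3 had a promoter summit (odds ratio 2.82, exact test, adjusted p = 0.201), nhr-25, elt-1 (signal 53.5) and nhr-23. Of 25 Wnt pathway genes 5 had one (odds ratio 2.58, exact test, adjusted p = 0.143), the strongest at mig-5 (66.997, shared with cct-1) and lin-18 (45.8). Of 15 insulin and stress pathway genes 3 had one (odds ratio 2.58, exact test, adjusted p = 0.217), hlh-30 (77.4), skn-1 (45.8) and akt-2. All 3 lists passed the exact test with a 2000 bp window (adjusted p = 0.00984, 0.0147 and 0.0131) and with assignment to the nearest gene start.

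For hedgehog-related and patched-related genes the count was 7 of 85 (odds ratio 0.926, exact test, adjusted p = 1), the strongest at ptr-13 (59.2) and hog-1 (54.5). For homeobox genes it was 3 of 81 (odds ratio 0.396, exact test, adjusted p = 0.201), with lin-39 (76.9) and ceh-20 (54.5). For distal tip cell migration genes it was 1 of 14, lin-29 (odds ratio 0.793, exact test, adjusted p = 1). The intestinal, muscle, neuronal, germline and oocyte, sperm and histone lists did not pass the exact test (adjusted p from 0.201 to 1). Intestinal markers had 1 of 17 (asp-1, signal 30.8), body wall muscle markers 1 of 19 (act-4, 30.9), and neuronal markers 1 of 25 (snb-1, 92.8), with odds ratios of 0.645, 0.573 and 0.430. Germline and oocyte genes had 3 of 27 (odds ratio 1.29), with cgh-1 (46.8) and spn-4 (32.9, shared with spe-39). Sperm genes had 3 of 82 (odds ratio 0.391, exact test, adjusted p = 0.201), with spe-54 (65.5) and spe-46 (34.8, shared with hgo-1). Histone genes had 4 of 72 (odds ratio 0.606), with his-37 (138) and his-67 (48.8, shared with his-68 and alg-5).

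**Figure D1:**
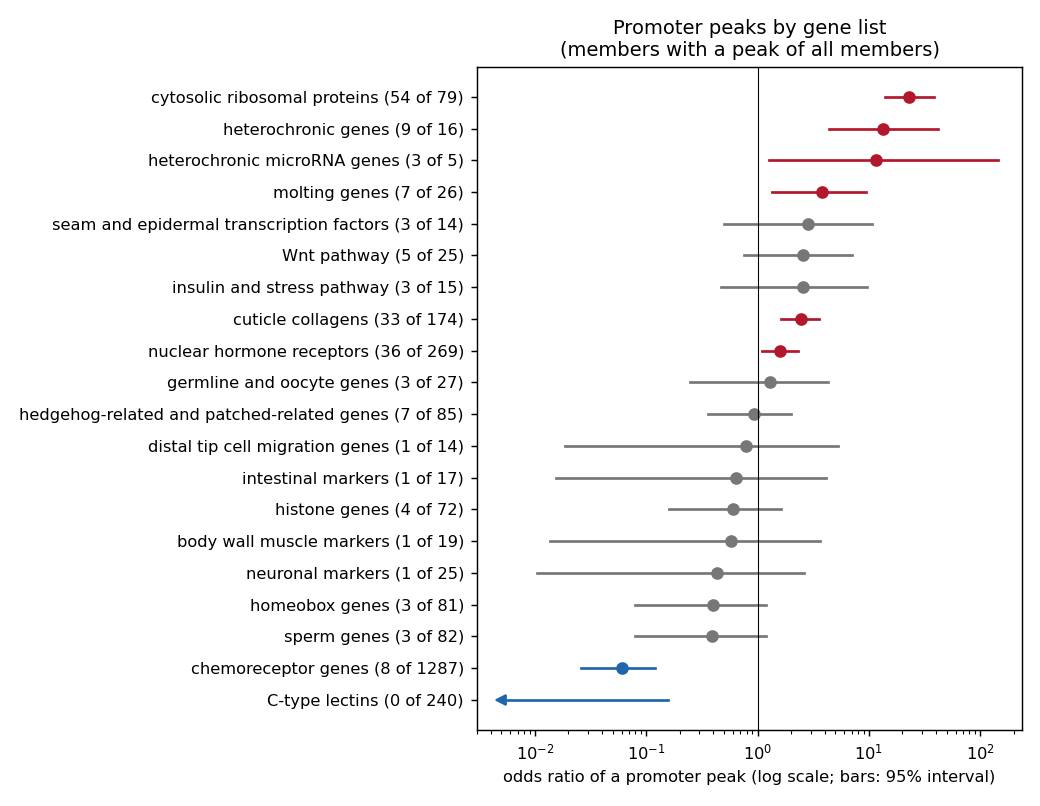
Odds ratio of a promoter summit for each of the 20 gene lists against all other genes of the same kind, on a log axis, with 95% intervals as bars; red marks lists above 1 and blue lists below 1 at an adjusted p under 0.05, and a triangle marks an estimate of 0 drawn at the axis floor. The cytosolic ribosomal protein list lies highest at 22.9, and the C-type lectin list, with 0 of 240 members, lowest.

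The next comparison asked whether summits carried the core of the mammalian PRDM1 consensus, AGYGAAAG on either strand. The word was within 50 bp of 215 of 3031 nuclear summits (7.09%, 95% Wilson interval 6.23 to 8.06), and in 18 of the paired windows 1000 bp to the left (0.594%, 0.376 to 0.937). The share was 11.9 times as high at summits (exact McNemar test, two-sided, p = 1.47e-44). Windows to the right gave 29 (0.957%, exact McNemar p = 2.80e-36). Summit windows were richer in G and C (43.5% against 36.5% in the left windows). In a scan of 32718 8-mers AGTGAAAG ranked 11, with 175 summit windows against 14 left windows, and the other form of the motif, AGCGAAAG, ranked 184. Of 279 other words of the same base composition, 1 had a difference as large.

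Without a choice of motif, the highest rank in the scan went to AGACGCAG, in 244 summit windows and 16 left windows (adjusted p = 5.14e-51, exact McNemar test). GAGAGAGA ranked 3 (276 against 36), and AAGTGAAA, which overlaps the PRDM1 core, ranked 4 (264 against 31). Stronger peaks carried AGYGAAAG more often. The share was 15.02% (95% Wilson interval 12.4 to 18.1) in the strongest quintile of peaks and 3.29% (2.14 to 5.03) in the weakest, where the left windows held 0.824% (0.352 to 1.91). Spearman's rho across peaks was 0.152 (two-sided permutation test, p = 1e-05, the smallest value that 100000 permutations can give). Peaks are not independent replicates, since they cluster along the chromosomes. Of the 10 strongest promoter peaks, those at W03F8.4, edc-4, dpy-31 and atf-2 carried the word.

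**Figure D2:**
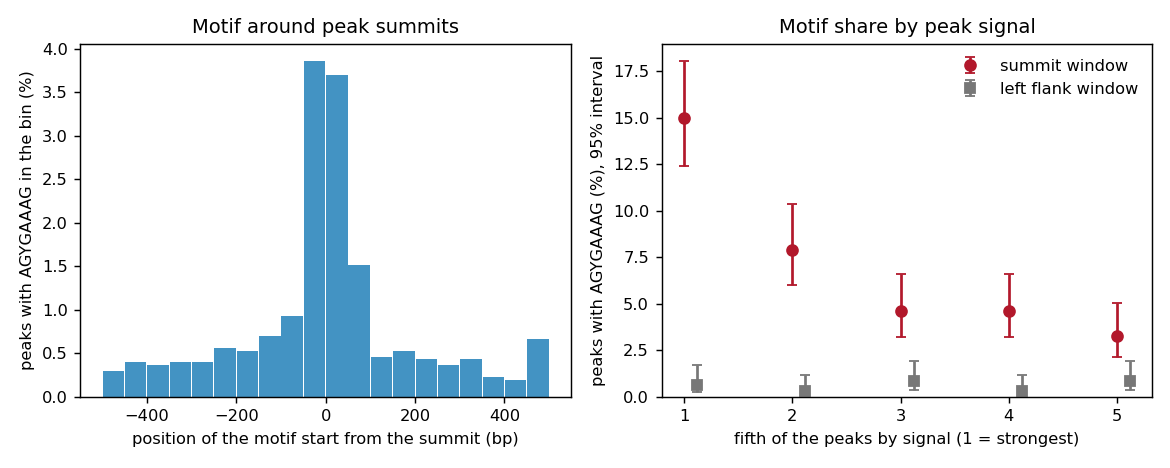
Left, percent of the 3031 nuclear peaks with an AGYGAAAG start in each 50 bp bin around the summit; right, percent with the word within 50 bp of the summit (red) and in the left flank window (grey) for each quintile of the peaks by signal, with 95% Wilson intervals. The share falls from 15.02% in the strongest quintile to 3.29% in the weakest, which stays above the flank value of 0.824%.

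The X chromosome held more summits than its share of promoter sequence. It carried 663 of the 3031 nuclear summits (21.9%, 95% Wilson interval 20.4 to 23.4) against 14.8% of the promoter window length (exact binomial test, two-sided, p = 1.49e-25). Against its share of chromosome length, 17.7%, the excess was smaller (exact binomial p = 3.86e-09). The density was 37.4 summits per Mb on X and 28.7 per Mb over the autosomes. Chromosome III had 35.1 per Mb, and chromosome V had the lowest density at 23.5 per Mb. Within promoter windows X had 76.3 summits per Mb of window and chromosome III had 77.2. The heterochronic genes lin-14, daf-12, kin-20, hbl-1, alg-1 and ain-1 lie on X. The test treats summits as independent, although they cluster.

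The tagged gene itself had a run of peaks. From 10000 bp upstream of the start of blmp-1 (chromosome I, 10409302 to 10414773, plus strand) to its end there were 11 thresholded summits, 9 upstream and 2 within the gene. The upstream summits reached 721, 505 and 421, and those in the gene had signals of 353 at 10409750 and 37.9 at 10411981. The summit of 240 farthest upstream in this window, at 10400788, lay in the promoter windows of cup-2 and tag-353. At unc-119 (chromosome III, 10902641 to 10908935, plus strand), the gene mutated in this strain, 1 summit of 37.1 lay within the gene and none in the promoter window. The strain carries additional copies of both blmp-1 and unc-119 through the transgene, and the ends of that insert are not given in the sources used here. Extra copies and binding therefore cannot be told apart at either gene.

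**Figure D3:**
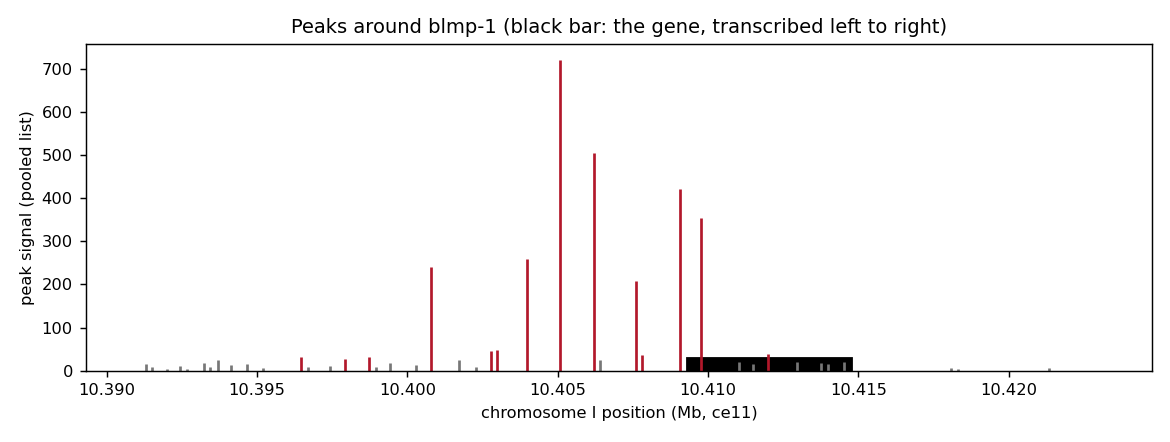
Signal of each pooled-list peak (vertical lines at the summits) against position on chromosome I in Mb on ce11; red lines reach the lowest signal of the thresholded list, grey lines do not, and the black bar is blmp-1. The highest line, 721, stands upstream of the gene.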

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

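The test of how much mitochondrial sequence the peaks cover, the counts of exact motif sites in that sequence and upstream of blmp-1, the test of the motif in ribosomal protein promoters, and the comparison of signals upstream of blmp-1 and within it were chosen after the peaks had been seen. The comparisons of motif shares at both places, which the counts replaced, are not counted as set in advance either. The tests of the ribosomal protein list and of the motif in the weakest quintile were written down before their results.

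Signal appeared in data outside the main measurement, as 29 thresholded peaks on mitochondrial DNA, with a median signal of 299 against 44.3 in nuclear peaks. They include the strongest peak of the list, 1574, and 4 of its 10 strongest. Binding of BLMP-1 at the exact word AGYGAAAG is argued against, since the 13794 bp sequence holds 0 such sites. The comparison of shares that this count replaced decides nothing, since without a site the share in these peaks is 0% by construction. Its interval (0 to 11.7) contains that of nuclear peaks (6.23 to 8.06). Abundance of mitochondrial DNA is a candidate explanation that the values fit, since the peaks covered 79.1% of the sequence. Few local sites would cover little of it, but 29 peaks cover much of so short a sequence whatever their source. The peaks were also called against a control library, which is not analysed here, so whether abundance alone would leave such peaks was not tested. Degenerate forms of the motif were not tested, and no biological explanation beyond the motif was.

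The run of strong peaks upstream of blmp-1 had a median pooled signal 2.37 times that of the peaks within the gene (14 peaks from 8.90 to 721 against 8 peaks from 15.9 to 353). Extra transgene copies raising the whole insert alike and local binding cannot be told apart by this value, since it lies between the bounds set for either, the sets overlap, and the ends of the insert are not given in the sources used here. Binding at the exact word AGYGAAAG is argued against as the source of the run, since the 10000 bp upstream of the gene hold 0 such sites in the reference sequence. The comparison of the 9 upstream thresholded peaks with their left windows, which that count replaced, had 0 carriers in each and decides nothing. Degenerate forms of the motif and other words were not tested at this locus. Most nuclear peaks lack the exact word, so binding without it stays open.

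Most peaks lacked AGYGAAAG. That the weaker peaks are all background is argued against, since 3.29% of the weakest quintile carried the word. The interval of that share (2.14 to 5.03) lay above that of their left windows (0.352 to 1.91). The right windows held 0.988%, a higher share than the left, for which no interval was computed. A count of carriers cannot test the peaks that lack the word, so background among these stays open. General pull-down at highly expressed genes may account for part of the motif-free peaks, since the odds ratio of the cytosolic ribosomal protein list was 22.9, although it fell to 6.98 with assignment to the nearest gene start. Of the 51 peaks in those promoters 1 carried the word (1.96%), against 6.16% of other promoter peaks (Fisher's exact test, p = 0.363). The muscle and intestinal markers, which also include abundant transcripts, had odds ratios of 0.573 and 0.645 with upper bounds of 3.63 and 4.15. Each rests on 1 gene, and both were 0 without replicate 2 (0.593 and 0.667 without replicate 3), while the intestinal value was 1.04 with the nearest gene start, so these lists decide nothing. Binding of BLMP-1 at ribosomal protein promoters without this word stays open.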

How the results depend on the processing

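The alternatives without peaks near blmp-1, with 1 summit per merged region, and of the motif and signal relation in single replicates were chosen after the data were seen. The replicate overlap, promoter share, motif share, motif and signal relation and X share kept their direction and their side of the threshold under every alternative run. Between the replicates taken alone, the promoter share ranged from 48.3% to 49.5%, the genes with a promoter peak from 1694 to 1711, the lists past the threshold from 5 to 8, the motif share from 6.46% to 6.67%, rho from 0.141 to 0.157 and the X share from 22.0% to 23.3%. Leaving out a replicate gives no replicate overlap. With the stronger 1530 peaks the genes with a promoter peak fell to 873 and the lists past the threshold to 5, and fewer peaks by construction give fewer genes. Taking the strongest peaks of the pooled list returned the thresholded list itself and tests nothing, and the X share on ce10 was not run because no ce10 lengths were given. In 14 cases an odds ratio crossed 1, in 6 lists that passed the threshold neither before nor after (lowest adjusted p 0.132), and the cause was not tested. For hedgehog-related and patched-related genes it became 1.08 (2000 bp), 1.68 (nearest start), and 1.78 and 1.11 without replicate 2 or 3. For distal tip cell migration genes it became 1.04 (500 bp), 1.30 (nearest start) and 1.78 without replicate 3, but stayed below 1 at 0.830 without replicate 2. For germline and oocyte genes it became 0.522 (500 bp), 0.841 (stronger peaks), 0.625 (nearest start) and 0.863 without replicate 2, but stayed above 1 at 1.33 without replicate 3. It became 0.970 for the insulin and stress pathway (500 bp), 1.04 for intestinal markers (nearest start) and 1.54 for histone genes without replicate 2 (0.463 without replicate 3). Of 80 genes named for a promoter window (5 of them after their values were seen), the presence of a promoter summit changed in 22 with the 500 bp window, 4 with the 2000 bp window, 15 with the stronger peaks, 5 without replicate 2 (act-4, asp-1, hbl-1, spe-39 and spn-4) and 6 without replicate 3 (hog-1, lin-28, lin-4, mir-84, nhr-23 and srh-46). Of the remaining odds ratios of single lists, 9 fell short of the threshold they had passed and 6 passed it newly. Depth is unknown, so a gene without a peak is not shown to be unbound.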

Other observations

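The values in this part were all singled out after the data were seen. Gene-name families with at least 10 members were scanned for promoter summits (170 families, Fisher's exact test, Benjamini-Hochberg). Beyond the ribosomal protein families rpl- (30 of 45) and rps- (24 of 31), summits were more frequent in the dpy- genes named for short, stout bodies (11 of 25, odds ratio 8.15, exact test, adjusted p = 9.77e-05) and the lin- genes named for cell lineage defects (16 of 45, odds ratio 5.73, adjusted p = 2.38e-05). Genes of the proteasome regulatory particle, rpn-, had 6 of 13 (odds ratio 8.87, exact test, adjusted p = 0.00725), and DnaJ chaperone genes, dnj-, had 9 of 29 (odds ratio 4.66, adjusted p = 0.00892). The F-box family fbxa- had 2 of 170 (odds ratio 0.122, exact test, adjusted p = 0.000832). These families overlap the fixed lists in part, as dpy- holds cuticle collagens and lin- holds heterochronic genes.

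In the 8-mer scan, AAGTGAAA and AGACGCAG stood together at 12 summits, where 21.3 would be found if they were independent (odds ratio 0.520, Fisher's exact test, unadjusted p = 0.0321). Other pairs of words were not tested. Of the 51 summits in promoters of cytosolic ribosomal proteins, 0 carried AAGTGAAA, against 8.86% of all other summits. GAGAGAGA was carried by 0 of the 51, against 9.26% (Fisher's exact test, adjusted p = 0.0302 over 3 words for each). AGACGCAG was carried by 2 (Fisher's exact test, adjusted p = 0.432). The other summits included those outside promoter windows, so these contrasts do not separate ribosomal protein promoters from promoters in general. Summits with GAGAGAGA lay in promoter windows less often than those without (40.6% against 50.9%, Fisher's exact test, adjusted p = 0.00376), while the share for AAGTGAAA was 44.3% (adjusted p = 0.0925). The median signal was 59.1 with AAGTGAAA and 43.0 without it.

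Several strong peaks stood outside promoter windows. Peaks of 526, 369 and 359 on chromosome V lay between 1626 and 4634 bp from the nearest transcript start, that of bcl-11, and all carried AGYGAAAG. A peak of 431 lay 3102 bp from fos-1.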
